A study of Drosophila melanogaster with 3 samples.

How the data were processed

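Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos of mixed sex, collected 0 to 24 h after laying. The embryos came from a transgenic line expressing the homeodomain protein HHEX (CG7056) with GFP at its C-terminus. Per the labels, the antibody was against GFP, chromatin was sheared by sonication to 200 to 800 bp, and there were 3 biological replicates of 1 group. The series has no second condition, so the comparisons made here are between replicates, between peaks and lower-ranked regions, between groups of genes, and between peak summits and their flanks.

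The deposited files are lists of regions on the dm6 and dm3 builds. Each replicate has a list of 30000 regions, made by the authors as peaks and background for the irreproducible discovery rate (IDR) procedure. A list of 30000 regions was made from the pooled reads of the 3 replicates. Per the deposited file descriptions, the thresholded IDR list derives from the replicate and pooled lists, and all replicates were called against the same control alignment, which was not analysed here. Regions enriched in any immunoprecipitation with this antibody could therefore not be told apart from HHEX sites, and bound means only that a peak was called. The aligner, peak caller and IDR threshold are not given in the sources used here. The signal of a region is the deposited value of the authors' peak caller. It was used to rank, describe and filter regions within a list. Means of it over the 3 replicate lists are given for named peaks as a description; the values were not rescaled between lists, so their SD includes any difference in scale. The −log10 q of a region is likewise deposited by the authors and has a ceiling in each list. Read depth is unknown, since the files give regions and not reads. As a description of each list, the number of regions with a −log10 q of at least 2 is given.

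Main results use dm6. Regions were annotated with Ensembl release 115 (build BDGP 6.54), and sequence came from genome release 6. Every dm6 region lay on the 6 arms X, 2L, 2R, 3L, 3R and 4. Annotated transposable elements were left out of genes and transcription start sites (TSSs), leaving 23581 distinct TSSs and 13945 protein-coding genes. Nothing was converted between builds. Regions of the pooled list that overlapped no IDR peak, 23262 in number, served as the background under the threshold.

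Replicates were compared over the 5586 highest-signal peaks of each, as many as there are IDR peaks, with an overlap of at least 1 bp counted as shared and chance taken from 100 shuffles of positions within arms. Signals at IDR summits were compared by Spearman's rho across peaks, without a p, because peaks are not independent replicates. A promoter peak has its summit within 500 bp of a TSS. Shares of locations, arms and bound genes were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. Median signals were compared with a two-sided permutation test of 100000 resamples. A gene was called bound when an IDR summit lay within 1000 bp of one of its TSSs, and each of 27 gene lists was tested against all other protein-coding genes. Odds ratios had 0.5 added to each cell, with Woolf 95% intervals. For sequence words, the 200 bp at each summit were compared with the 2 flanks 500 to 600 bp away on either side by an exact McNemar test, two-sided, for 16 words fixed in advance and for all 2080 6-mers, with either strand counted. Summits were compared with GC-matched regions, from a single random draw, by Fisher's exact test. The gene lists, words, tests and alternatives were fixed before the data were examined, and a few gene symbols were afterwards changed to those of the annotation. Tests treat peaks and genes as units, so their p-values describe these lists. The spread between replicates is given for the promoter share, for arms X and 4, for the ribosomal protein, receptor and cuticle lists and for the words YATTAAR, TATCGATA, GGTCACAC and AAATAT, and not for the other tested shares.

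Named genes followed a fixed rule. HHEX was named, then the protein-coding gene with the nearest TSS for each of the 20 highest-signal IDR peaks found in all 3 replicates, then up to 4 bound members with the highest signal in each list that passed the test. Unbound members were to be named only for passing lists of under 40 genes, and no such list passed. The 5 enriched and 3 depleted 6-mers with the lowest p were also named. Genes outside the rule were chosen after their values were seen, and are stated to be so.

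The 6-mer test was tested on simulated data made from 5573 random genomic positions. A word planted in 4% of centres was called and ranked 1 among 2080 words, with 0 unrelated words called. Random positions lack the A/T-rich centres of the real summits. The 0 unrelated calls therefore do not carry over to words that follow base composition. The gene list test was tested on 100 simulations per setting over 13945 genes. At that number of genes a list of 92 members was called in 41% of simulations at a true odds ratio of 2 and in 100% at a true odds ratio of 4.

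Alternatives covered the build, a stricter set of the 2793 IDR peaks with higher signal, other windows, flanks and overlaps, other backgrounds (random positions, arm length, genes with a pooled region, GC-matched regions), lists matched on the number of TSSs, and leaving out each replicate. The IDR list could not be called again without a replicate. Peaks whose summit lay in the 5586 highest peaks of both other replicates stood in for it, 3786, 4017 and 3656 peaks without replicates 1, 2 and 3. Such sets are also stricter than the IDR list. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.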

Results

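HHEX-GFP peaks were mapped in whole embryos of 0 to 24 h in 3 biological replicates. HHEX is a homeodomain protein, a class of transcription factor that binds A/T-rich DNA words. The IDR list on dm6 held 5586 peaks with a median width of 424 bp, and these were the 5586 regions of highest signal in the pooled list. On dm3 the list held 4777 peaks. Read depth is unknown. Regions with a −log10 q of at least 2 numbered 9759 in replicate 1, 3212 in replicate 2 and 6498 in replicate 3, so replicate 2 gave the fewest at the caller's own scale.

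The first question was how far the replicates mark the same sites. The highest peak in each of the 3 replicates lay at the TSS of Ugalt, a UDP-galactose transporter gene, and the peaks in the intron of CG11050, at the promoter of CG14100 and beside cbt, a zinc finger transcription factor gene, ranked 2 to 4 in every replicate. Among the 5586 highest peaks, 77.3% were shared between replicates 1 and 3, 71.6% between 2 and 3, and 69.1% between 1 and 2, a mean of 72.7% ± 4.18 (SD, 3 pairs). Position shuffles gave a mean of 3.14% and a highest value of 3.50%. Of the IDR peaks, 5020 (89.9%) had their summit in a region of all 3 replicate lists. Those lists include background regions, and the IDR list derives from them. Fewer IDR peaks, 3293 (59.0%), had their summit among the 5586 highest peaks of all 3 replicates. Across the 5020 peaks Spearman's rho of the signal was 0.772 for replicates 1 and 3. It was 0.70 for 2 and 3, and 0.660 for 1 and 2. Pairs with replicate 2 were lower both in the share of highest peaks and in rho.

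The 20 strongest peaks found in all 3 replicates lay near 20 genes, and 12 had promoter summits. The Ugalt peak (FBgn0024994, X, 2703658 to 2704095) had a signal of 5323 in the pooled list and 1783 ± 197 (SD, n = 3) in the replicate lists, with its summit 35 bp from the TSS. The peak nearest cbt (FBgn0043364, 2L, 480860 to 481319) lay in an intron of ush, a zinc finger gene, 1368 bp from the cbt TSS, with a signal of 4417 in the pooled list and 1451 ± 54.1 in the replicates. The CG11050 peak (FBgn0031836, 2L, 6612499 to 6612923) was intronic, with a replicate signal of 1432 ± 36.2. The CG14100 peak (FBgn0036889, 3L, 19590424 to 19590819) was at the promoter, with a replicate signal of 1414 ± 285. Next were hll, CG4004 and px. The summit nearest hll lay 2916 bp from the hll TSS, within the long noncoding RNA gene CR31840 and within 500 bp of another TSS. The summit nearest CG4004 lay in an exon of the long noncoding RNA Vinr, 5000 bp from the CG4004 TSS. Trl, the GAGA factor gene, had an intronic peak (3L, 14759304 to 14759742) with a replicate signal of 1036 ± 70.0. The peak at ph-p, a Polycomb group gene, was at its promoter (X, 2137157 to 2137551) with 1010 ± 170. Chro, which encodes the chromosomal protein Chromator, had a promoter peak (3L, 22878701 to 22879098) with 931 ± 93.2, and HmgZ, an HMG box gene, had an intronic one (2R, 21703129 to 21703684) with 885 ± 164. Promoter peaks also lay at PNPase, which encodes an RNA exonuclease, mRpL41, which encodes a mitochondrial ribosomal protein, CenG1A, CG1888, CG18549 and Art3, an arginine methyltransferase gene. Intronic ones lay in Lk6, a kinase gene, CG32772 and CG9663. Signals of the 20 peaks ranged from 2578 to 5323, against a median of 255 over all IDR peaks. Their lowest rank was 28 in replicate 1, 36 in replicate 2 and 27 in replicate 3.

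The next comparison was where in the genome the peaks lie. Promoters held 2537 of the 5586 summits (45.4%), against 23.5% of regions under the threshold. The odds ratio was 2.70 (95% interval 2.54 to 2.87, Fisher's exact test, adjusted exact p = 4.71e-219). The share was 48.4%, 41.9% and 46.5% in the 5586 highest peaks of replicates 1, 2 and 3, a mean of 45.6% ± 3.34 (SD, n = 3), so the difference from the background was larger than the spread between replicates. Introns held 38.7% of IDR summits against 45.8% of the background, and intergenic sequence 12.9% against 21.7%. Coding exons held 21 summits (0.376%) against 4.70% (odds ratio 0.0783, adjusted exact p = 1.21e-74). The median distance from summit to TSS was 659 bp for IDR peaks and 1994 bp for the background.

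**Figure D1:**
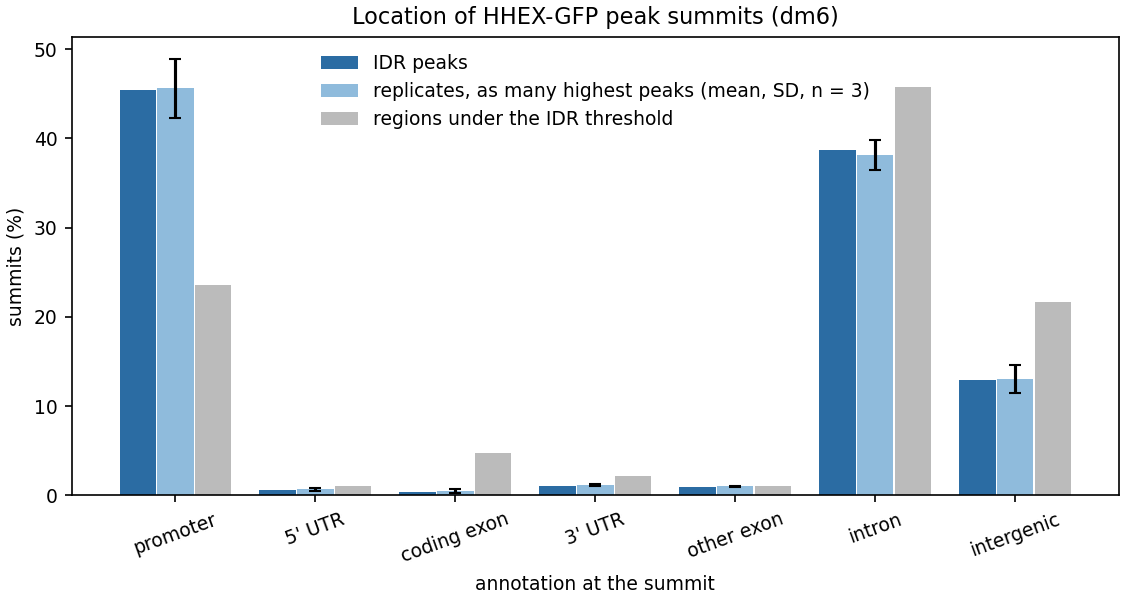
Share of summits (%, vertical axis) in each annotation class (horizontal axis) for the IDR peaks, the 5586 highest peaks of each replicate (mean with SD, n = 3) and regions under the IDR threshold. The promoter bars stand at 45.4%, 45.6% and 23.5%.

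Promoter peaks were stronger than other peaks in the IDR list, with a median signal of 271 against 244, a difference of 26.8 (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples give). The difference had the same sign in the 3 replicate lists, at 2.36 in replicate 1 (permutation p = 0.0647), 21.7 in replicate 2 (permutation p = 1e-05) and 6.28 in replicate 3 (permutation p = 2e-05). Replicate 1 on its own did not pass the threshold. The difference was 55.0 in the peaks kept without replicate 1, 35.3 without replicate 2 and 59.1 without replicate 3 (permutation p = 1e-05 each), sets that hold stronger peaks by construction.

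Shares of the chromosome arms were compared with those of the regions under the threshold. X held 17.7% of IDR peaks against 16.2% of the background (adjusted exact p = 0.0510), 2L 18.6% against 19.1%, 2R 18.0% against 18.1%, 3L 21.4% against 22.5% and 3R 24.1% against 23.8%. The small arm 4 held 9 peaks (0.161%) against 0.361% (adjusted exact p = 0.0517), or 6.68 peaks per Mb, where the other arms had 39.9 to 44.2 per Mb. In the 5586 highest peaks of the replicates X held 17.2% ± 0.407 and arm 4 0.286% ± 0.124 (SD, n = 3), so arm 4 lay within 1 SD of the background. By Fisher's exact test 0 arms passed after adjustment and 2, X and 4, had an unadjusted p under 0.05. These calls turned on the settings. X passed in the 2793 peaks with higher signal (18.2%, adjusted exact p = 0.0410), on dm3 (18.1%, adjusted exact p = 0.0378), without replicate 1 (18.6%, adjusted exact p = 0.00183) and without replicate 3 (18.9%, adjusted exact p = 0.000381), but not without replicate 2 (17.6%, adjusted exact p = 0.0802) or against arm length (17.7% against 17.6%, adjusted exact p = 0.888). The lower share of 3L passed on dm3 (21.1%, adjusted exact p = 0.0378) and without replicate 1 (20.4%, adjusted exact p = 0.00948) or 2 (20.6%, adjusted exact p = 0.0426). The lower share of arm 4 passed without replicate 1 (0.106%, adjusted exact p = 0.0160) or 3 (0.109%, adjusted exact p = 0.0344), and against its length (adjusted exact p = 7.48e-14). Neither 3L nor arm 4 passed in the remaining settings.

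The gene lists asked which kinds of gene carry a peak at a TSS. Ribosomal protein genes stood apart: 78 of 92 (84.8%) were bound, against 22.8% of other genes (odds ratio 18.4, 95% interval 10.5 to 32.2, Fisher's exact test, adjusted exact p = 1.43e-34), and 79.0% ± 4.39 (SD, n = 3) were bound in the replicates. Bound here means a called peak, and regions enriched in any anti-GFP immunoprecipitation could not be separated, for these genes or for the strongest peaks. The strongest of these peaks lay at the TSSs of RpS27 (FBgn0039300, 3R, 25247342 to 25247711, replicate signal 618 ± 144, 1 bp from the TSS), RpL7 (FBgn0005593, 2L, 10200886 to 10201210, 543 ± 71.2, 47 bp), RpL14 (FBgn0017579, 3L, 8600823 to 8601120, 442 ± 45.7, 14 bp) and RpL23A (FBgn0026372, 3L, 1668565 to 1668891, 419 ± 83.2, 66 bp). The highest peak at a bound ribosomal protein gene had a median signal of 532, against 291 at other bound genes (permutation p = 1e-05, the smallest possible). Over all 13945 protein-coding genes, 3233 (23.2%) were bound.

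Receptor, cuticle and histone genes were bound less often than other genes. Of 119 odorant and gustatory receptor genes 4 were bound (3.36%, against 23.4% of other genes, odds ratio 0.128, adjusted exact p = 1.64e-08), with 2.80% ± 0.485 (SD, n = 3) in the replicates. These were Or88a, Gr32a, Gr64a and Or9a, whose summits lay 593 to 996 bp from the receptor's TSS and within 500 bp of another TSS. Among genes with a region of the pooled list near a TSS the receptor list no longer passed (21.1% bound against 43.6% of other genes, adjusted exact p = 0.380). Of 92 cuticle protein genes 1, Cpr73D, was bound (1.09%, odds ratio 0.0539, adjusted exact p = 1.02e-08), with 1.45% ± 0.628 in the replicates. Of 111 replication-dependent histone genes 0 were bound (adjusted exact p = 3.61e-12), with an exact 95% upper limit of 3.27%. These histone genes are near-identical copies, and 0 of the 111 had any of the 30000 pooled regions near a TSS, so their state is uncertain.

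The other 23 lists did not pass after adjustment. Hox genes had 0 of 8 bound (adjusted exact p = 0.437, exact 95% upper limit 36.9%) but 4 of 8 within 5000 bp of a TSS or over gene bodies (adjusted exact p = 0.832 and 0.435), pair-rule genes 1 of 9 (hry, the hairy gene), segment polarity genes 1 of 12 (nkd), gap and terminal genes 4 of 14 (cnc, hb, bcd and cad), neural regulators 3 of 22 (elav, pros and grh) and homeobox genes outside the Hox cluster 8 of 69 (11.6%, adjusted exact p = 0.0924), a list that passed as bound less often within 5000 bp of a TSS (adjusted exact p = 0.000237) and against random lists matched on TSSs (mean of 17.2 bound, adjusted permutation p = 0.0281), and in none of the other settings. Polycomb and Trithorax genes had 7 of 13 bound (53.8%, odds ratio 3.83, adjusted exact p = 0.0868), namely ph-p, brm, ph-d, E(z), Trl, Psc and Su(z)12, and the result depended on the setting. The list passed over gene bodies (adjusted exact p = 0.00338), in the 2793 peaks with higher signal (adjusted exact p = 0.00466), within 500 bp (adjusted exact p = 0.0348) and without replicates 1, 2 and 3 (adjusted exact p = 0.0130, 0.0194 and 0.0102), and did not pass within 5000 bp (adjusted exact p = 0.0799), against random lists matched on TSSs (adjusted permutation p = 0.309) or among genes with a pooled region (adjusted exact p = 0.686). Endoderm and gut regulators had 6 of 11 bound (54.5%, adjusted exact p = 0.0924), namely fkh, bowl, Hnf4, GATAe, lin and cad, and passed in no setting: 3 of 11 were bound without replicate 1 (adjusted exact p = 0.648) and 4 of 11 without replicate 2 or 3, and random lists matched on TSSs had a mean of 37.6% bound (adjusted permutation p = 0.645). Members in these sentences were chosen after their values were seen. Wnt pathway genes had 9 of 25 bound, Notch pathway genes 7 of 18, heat shock genes 5 of 13, ecdysone response genes 4 of 11 (9 of 11 over gene bodies, adjusted exact p = 0.00338), trachea and salivary gland regulators 4 of 9, mesoderm and muscle regulators 4 of 15, muscle structural genes 3 of 13, dorsoventral patterning genes 4 of 20, heart regulators 2 of 9, blood cell regulators and markers 2 of 16, JAK/STAT pathway genes 1 of 7, cell cycle genes 4 of 14, germline genes 3 of 9 and proteasome genes 5 of 48. Tests over gene bodies were not matched on gene length. Ecdysone response genes did not pass against random lists matched on TSSs, with 36.4% bound against a mean of 46.5% (adjusted permutation p = 0.870). In the chorion and yolk list 1 of 14 was bound, Cp190, which encodes an insulator protein and entered that list by its name.

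**Figure D2:**
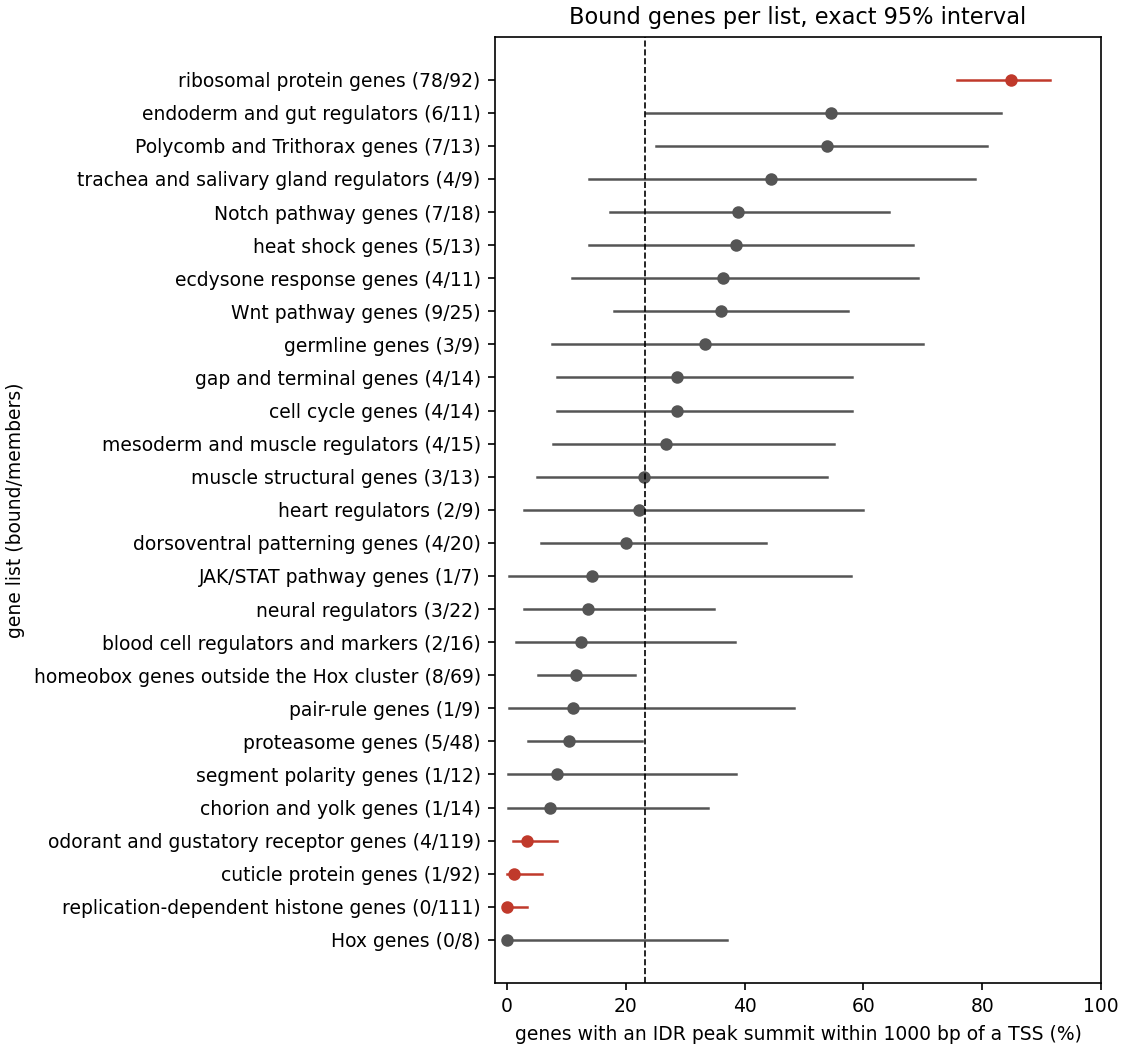
Share of genes with an IDR summit within 1000 bp of a TSS (%, horizontal axis) for each gene list (vertical axis, bound and total members in brackets), with exact 95% intervals. The dashed line marks 23.2% over all protein-coding genes, red marks an adjusted p under 0.05, and ribosomal protein genes stand at 84.8%.

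The locus of HHEX itself was examined for peaks of its own protein. HHEX (FBgn0038852, 3R, 21076862 to 21080926) had an IDR peak at 21081111 to 21081534, with its summit at 21081323, 397 bp from the TSS. Its signal was 228 in the pooled list, rank 3290 of 5586, and the same site held a peak at rank 4632, 2244 and 4836 in replicates 1, 2 and 3. Within 25 kb of the gene there were 3 IDR peaks, and 53.9% of other protein-coding genes had as many or more. The flies were transgenic for the tagged HHEX, and reads from a transgene copy would map to this locus too. Binding of HHEX at its own gene therefore could not be told apart from an effect of the transgene.

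Words of the homeodomain class were then compared between summits and flanks. YATTAAR (Y is C or T, R is A or G), the longest of the 5 homeodomain words, was in 27.4% of summits and 18.8% of flanks (ratio 1.46, exact McNemar test, adjusted exact p = 1.51e-25), with 26.6% ± 1.29 and 19.1% ± 0.0807 (SD, n = 3) in the replicates. TAATTA was in 16.9% and 12.6% (adjusted exact p = 5.35e-10), CATTAA in 16.6% and 13.9% (adjusted exact p = 0.000157) and TTATTG in 21.5% and 19.7% (adjusted exact p = 0.0196), each higher at summits in 3 of 3 replicates. Outside promoters CATTAA and TTATTG did not pass (adjusted exact p = 0.879 each). CAATTA was in 19.2% and 19.0% (adjusted exact p = 0.904). Summits were A/T-rich, with a mean GC content of 37.1%, against 42.4% in regions under the threshold. Against 5581 regions under the threshold with the same GC content, 0 of the 5 homeodomain words were enriched: YATTAAR was in 27.3% of summits and 26.3% of matched regions (adjusted exact p = 0.309), TAATTA in 16.9% and 17.0% (adjusted exact p = 0.896), and CAATTA was lower at summits (19.2% against 21.3%, adjusted exact p = 0.0124).

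Among the other 11 words, core promoter words had the highest ratios. The DNA replication-related element TATCGATA was in 2.38% of summits and 0.555% of flanks (ratio 4.29, adjusted exact p = 7.30e-16), and the motif 1 word GGTCACAC, bound by M1BP, in 1.97% and 0.448% (ratio 4.40, adjusted exact p = 3.54e-14). In the replicates TATCGATA was in 2.30% ± 0.207 and 0.543% ± 0.132 (SD, n = 3), and GGTCACAC in 1.81% ± 0.296 and 0.543% ± 0.122. With flanks taken nearer to the summit the ratios fell to 2.51 (adjusted exact p = 2.16e-09) and 2.29 (adjusted exact p = 9.40e-07). Both passed against GC-matched regions, at ratios of 1.96 (adjusted exact p = 1.56e-05) and 2.29 (adjusted exact p = 3.99e-06). Those regions were not matched on location, and promoters held 45.4% of IDR summits against 23.5% of regions under the threshold. No comparison here used promoters without a peak, so these words could not be separated from promoter location. TATCGATA was in 4.85% of promoter peaks and 0.328% of other peaks, and the odds ratio between them was 14.8 (95% interval 7.87 to 27.9, Fisher's exact test, adjusted exact p = 2.67e-30, a comparison added after the data were seen). Outside promoters the ratio of summits to flanks was 0.833 for TATCGATA and 1.25 for GGTCACAC (adjusted exact p = 0.879), and neither passed. CGATA, a word of the insulator protein BEAF, was in 26.2% and 22.4% (adjusted exact p = 4.49e-06). This word lies within TATCGATA, and outside promoters it did not pass (ratio 0.998, adjusted exact p = 1). The GATA word WGATAR (W is A or T) was in 38.9% and 31.7% (adjusted exact p = 3.27e-15) and CATATG in 8.31% and 7.14% (adjusted exact p = 0.0268), and neither passed against GC-matched regions (adjusted exact p = 0.419 and 0.285). CATATG also did not pass without any 1 of the replicates (adjusted exact p = 0.148 to 0.383). AGGAC was lower at summits (8.50% against 16%, adjusted exact p = 3.59e-33), as were GCCAT (26.6% against 34.4%), the E-box CANNTG (62.0% against 67.6%) and the repeat GTGTGTGT (4.69% against 6.77%). Against GC-matched regions CANNTG and GTGTGTGT did not pass (adjusted exact p = 0.258 and 0.461). The GAGA factor word GAGAG was in 25% of summits and 25.9% of flanks (adjusted exact p = 0.292), passed as lower in a 100 bp window (ratio 0.784, adjusted exact p = 8.32e-07), with flanks taken nearer to the summit (ratio 0.866, adjusted exact p = 5.17e-06) and without replicate 1 (ratio 0.911, adjusted exact p = 0.0243), and was higher than in GC-matched regions (20.5%, adjusted exact p = 2.59e-07). The Zelda word CAGGTAG was in 1.04% and 1.45% (adjusted exact p = 0.0640), and passed as lower in promoter peaks (ratio 0.512, adjusted exact p = 0.0147), in a 100 bp window (ratio 0.565, adjusted exact p = 0.0257) and in the 2793 peaks with higher signal (ratio 0.574, adjusted exact p = 0.0301). Against GC-matched regions its ratio was 1.35 (adjusted exact p = 0.258).

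**Figure D3:**
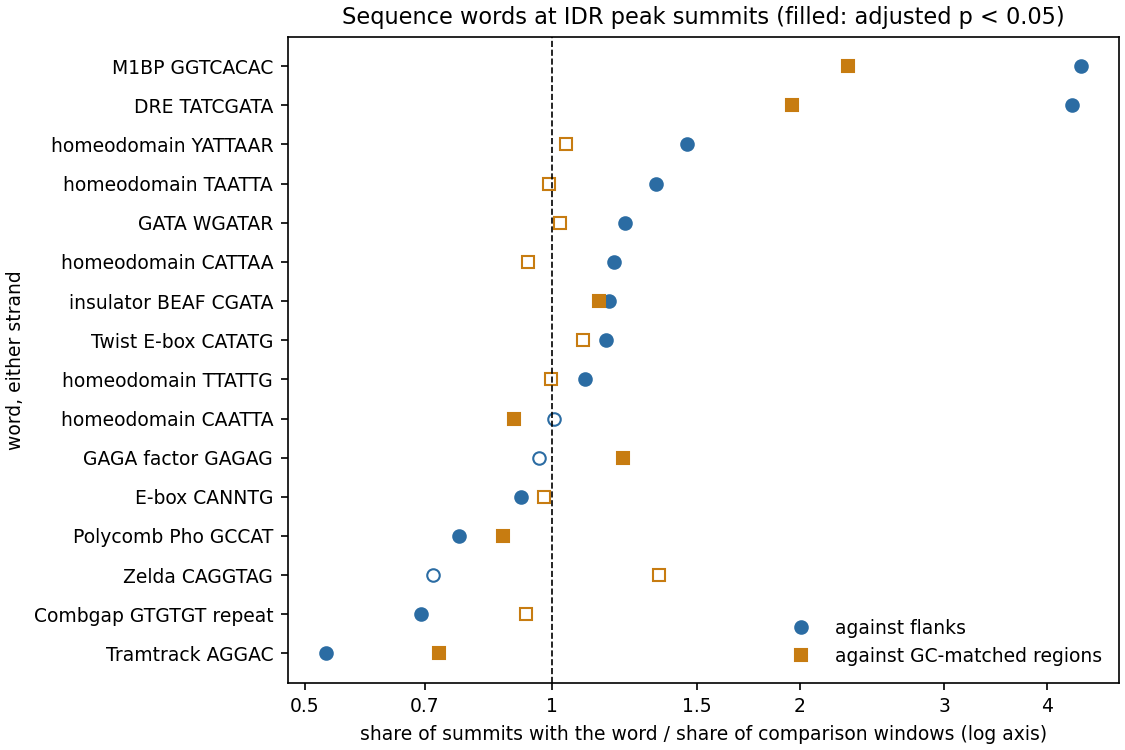
Ratio of the share of IDR summits with each word to the share of flanks (circles) or of GC-matched regions under the threshold (squares), on a log horizontal axis, for the 16 words (vertical axis). Filled symbols have an adjusted p under 0.05. The homeodomain words lie between 1.01 and 1.46 against flanks and between 0.900 and 1.04 against GC-matched regions.

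Of all 2080 6-mers, 487 were more frequent at summits than in flanks and 957 less frequent. The 5 with the lowest p were made of A and T: AAATAT (50.3% against 30.4%, adjusted exact p = 7.58e-96, with 49.0% ± 1.23 and 31.1% ± 0.798 in the replicates), TAAATA (45.0% against 28.3%), TTAAAA (44.1% against 27.5%), AAAATA (52.4% against 36.0%) and AATATA (35.9% against 21.0%). All 36 6-mers of A and T only were enriched. The depleted ones with the lowest p were GGAGGA (3.06% against 9.49%, adjusted exact p = 2.39e-43), CCAGGA (2.15% against 7.5%) and CGAGGA (2.69% against 8.27%). Against GC-matched regions 145 6-mers were enriched and 136 depleted. There ACAGTG (17.8% against 11.2%, ratio 1.59, adjusted exact p = 6.53e-20) and ACACTG (17.8% against 11.8%, ratio 1.5, adjusted exact p = 1.50e-15) had the lowest p. Of the 5 enriched 6-mers named above, TAAATA and TTAAAA still passed (ratios 1.09 and 1.07, adjusted exact p = 0.00463 and 0.0290), as did the 3 depleted ones, and AAATAT, AAAATA and AATATA did not (adjusted exact p = 0.166, 0.576 and 0.822).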

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

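On dm3, whose lists served only as alternatives, regions also lay outside the 6 main arms, on heterochromatic or unplaced scaffolds. Replicate 2 had 158 such regions, replicates 1 and 3 had 4 each, and the pooled list had 10. They were singled out because they stand above the limit of 3 that a count of 0 allows, in data no comparison above uses. In replicate 2 the highest of them ranked 2527 of 30000, 6 were among its 4777 highest regions, and 1 had a −log10 q of at least 2. Replicate 2 also had a lower share of its dm6 regions on X, 13.8% against 17.8% and 16.7% in replicates 1 and 3. No explanation of these values was tested.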

How the results depend on the processing

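Of the 565 values obtained under alternatives, 456 kept their direction and side of the threshold, or their size. The promoter share, the sign and test of the promoter signal difference, and the calls of ribosomal protein and cuticle protein genes were among those that kept both under every alternative. The histone call did not change, but with 0 of 111 genes near a pooled region its outcome in windows of up to 1000 bp was fixed in advance, and it gave no value among genes with a pooled region. The stricter set held 2793 peaks by construction. Replicate overlap was 64.4% with a reciprocal overlap of 50%, 80.3% for the 1000 highest peaks and 58.0% for all regions, and 69.1% to 77.3% when a replicate was left out, with rho from 0.660 to 0.772. Arms past the threshold numbered 1 against arm length, 1 in the stricter set, 2 on dm3 and 1 to 3 without a replicate. Gene lists past the threshold fell to 2 among genes with a pooled region. Enriched words fell to 3 in peaks outside promoters and 4 against GC-matched regions, where enriched 6-mers numbered 145 and depleted ones 136. Near HHEX there was 1 peak within 10 kb and there were 8 within 50 kb. In all 47 values changed direction, which for a gene list is that of its odds ratio with 0.5 added to each cell, or of its count against the mean of matched lists. Arm shares did so against arm length (2L 18.6%, 3L 21.4%), in the stricter set (2R 18.8%, 3R 23.2%) and on dm3 (2R 18.1%). Gene lists, given as bound shares, did so with a 5000 bp window (Hox 50%, gap and terminal 28.6%, dorsoventral 45%), with gene bodies (Hox 50%, gap and terminal 28.6%, dorsoventral 55%, JAK/STAT 28.6%), in the stricter set (gap and terminal 7.14%, JAK/STAT 14.3%, cell cycle 7.14%), among genes with a pooled region (pair-rule 100%, 1 of 1, mesoderm 40%, muscle structural 25%, cell cycle 36.4%, chorion and yolk 50%, 1 of 2) and against lists matched on TSSs (muscle structural 23.1%, heart 22.2%, ecdysone 36.4%, cell cycle 28.6%). Word ratios did so against GC-matched regions for 6 of the 16 words (ratios of 0.900, 0.934, 0.991, 0.997, 1.22 and 1.35), in promoter peaks (GAGAG 1.02) and in other peaks (CAATTA 0.974, TATCGATA 0.833, CGATA 0.998). When each replicate was left out in turn, JAK/STAT (14.3%) and cell cycle (7.14% to 14.3%) genes changed direction in all 3 sets. The other results given here as ranges over the 3 sets changed direction in some and kept it in others: 2R (18.0% to 18.7%) did so without replicates 1 and 2, gap and terminal genes (14.3% to 21.4%) without replicate 1, and 3R (23.3% to 24.1%), Wnt (12% to 24%), dorsoventral (10% to 15%) and CAATTA (ratio 0.973 to 1.02) without replicate 3. Of the 28 such values of gene lists, the share itself crossed that of the genes compared in 20. It did not for JAK/STAT over gene bodies or without replicate 1, 2 or 3, muscle structural genes in either setting, heart genes against matched lists or dorsoventral genes without replicate 3. It crossed in 17 others, among them gap and terminal genes without replicate 3, Wnt genes without replicate 1 and most settings of muscle structural and heart genes, whose main shares lay within 1 percentage point of other genes. Fewer peaks enter the sets without a replicate and the stricter set; for other changes the cause was not tested. Depth is unknown, so its limit on the weaker peaks cannot be given.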

Other observations

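The tests of low GC content and promoter location for CACTG were chosen after those results were seen, as were the gene groups and word comparisons in this part, while GC-matched regions for homeodomain words and the number of TSSs for ribosomal protein genes were comparisons fixed before the data were examined, taken as tests of an explanation only after their values were seen. No other group of broadly used genes tested differed from other genes after adjustment by Fisher's exact test: 15 of 53 translation factor genes (28.3%, adjusted exact p = 0.621), 19 of 84 oxidative phosphorylation genes (22.6%, adjusted exact p = 1) and 24 of 73 mitochondrial ribosomal protein genes (32.9%, adjusted exact p = 0.157). The strongest peaks among them lay at eIF2Bbeta, mRpL41 and mRpS23. The 92 promoter peaks within 1000 bp of a ribosomal protein TSS differed in sequence from the other 2445 promoter peaks. They held TATCGATA in 22.8% against 4.17% (odds ratio 6.88, adjusted exact p = 1.27e-08), CGATA in 59.8% against 31.1% (odds ratio 3.28, adjusted exact p = 3.10e-07) and GGTCACAC in 13.0% against 3.60% (adjusted exact p = 0.000917), and they held YATTAAR less often, in 12% against 29.0% (odds ratio 0.345, adjusted exact p = 0.000917), by Fisher's exact test over 17 words. The other words to pass were GCCAT, higher in ribosomal protein peaks (37.0% against 25%, adjusted exact p = 0.0343), and GAGAG (13.0% against 25.4%, adjusted exact p = 0.0223) and TTATTG (10.9% against 21.6%, adjusted exact p = 0.0343), both lower. GC content was not matched between these sets of peaks, and its part in the word differences, that of YATTAAR included, was not tested. Promoters without a peak were not compared, so these words could not be separated from the sequence of ribosomal protein promoters in general.

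The binding of 78 of 92 ribosomal protein genes was set against technical explanations. Broad use of a promoter was tested with the translation factor, oxidative phosphorylation and mitochondrial ribosomal protein genes together. If broad use alone gave the pattern, their bound share should reach 75.8%, the exact lower limit for ribosomal protein genes. Their exact upper limit was 34.2%, which argues against broad use alone. A partial contribution stays open, since their odds ratio to other genes was 1.28 (95% interval 0.941 to 1.73). Lists matched on GC content around the TSS reached at most 43 bound genes in 10000 draws, and lists matched on the number of TSSs at most 39. CACTG was in 40.2% of ribosomal protein peaks and 44.0% of other promoter peaks, an odds ratio of 0.860 (95% interval 0.564 to 1.31). These values argue against a large excess of CACTG at ribosomal protein peaks, while a small one stays open. Very high transcription, or enrichment in any anti-GFP immunoprecipitation, may also account for the pattern, since neither was measured here, and no biological explanation was tested because the design has 1 group.

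Low GC content alone could give the enrichment of homeodomain words at summits, since 0 of the 5 words were enriched against GC-matched regions. Those regions are lower-ranked regions of the same pooled list and may hold weaker HHEX sites. Equal word shares therefore cannot separate GC content from weaker binding. TAATTA ranked 34 of the 36 6-mers of A and T only by its ratio to flanks. That ranking covers TAATTA and not the other homeodomain words. Of the 6-mers held by some forms of YATTAAR, TATTAA ranked 8 and ATTAAA ranked 27 of the 36. The ranking was therefore mixed for parts of YATTAAR and does not decide whether low GC content accounts for that word. YATTAAR was in 31.6% of the 1117 peaks with the highest signal and 22.2% of the 1117 with the lowest (odds ratio 1.62, adjusted exact p = 1.13e-05). Stratified by GC content the odds ratio was 1.24 (95% interval 1.02 to 1.52, Mantel-Haenszel chi-square p = 0.0378, adjusted p = 0.129 over 17 words), so a relation of YATTAAR to peak strength beyond GC content stays open. No biological explanation was tested.

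CACTG, held on one strand or the other by the 3 6-mers with the lowest p against GC-matched regions (ACAGTG, ACACTG and CACTGA), was in 45.6% of summits and 30.7% of flanks (ratio 1.49, exact McNemar p = 2.12e-60), and the ratio was 1.43, 1.5 and 1.46 in replicates 1, 2 and 3. Against GC-matched regions its ratio was lower, at 1.29 (45.6% against 35.4%). CACTG was picked from GC-matched regions, so low GC content was tested by choosing the leading 6-mer on some arms and testing it on the others: ACAGTG, chosen on X, 2L and 2R, had a ratio of 1.45 on the other arms (Fisher's exact test, p = 3.56e-07), and ACACTG, chosen on 3L, 3R and 4, had 1.51 (exact p = 5.27e-11), which argues against low GC content as the whole cause. The ratio of CACTG to flanks was 1.66 outside promoters and 1.31 at promoter peaks. A word shared by promoters therefore does not account for the whole enrichment. Without the 36 summits in or within 200 bp of annotated transposable elements the ratio was 1.48. These summits were 0.644% of the 5586, too few to account for the difference, so this outcome was fixed by their number. Element copies that are not annotated were not examined. Whether CACTG goes with peak strength stays open. The odds ratio was 1.17 (95% interval 0.989 to 1.38) between the same 1117 highest and 1117 lowest peaks. Stratified by GC content it was 1.26 (95% interval 1.06 to 1.5, Mantel-Haenszel chi-square p = 0.00961, adjusted p = 0.116 over 17 words). No biological explanation was tested.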
